A study of Homo sapiens with 6 samples.

How the data were processed

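RNA of MDA-MB-231 cells, a human breast cancer line with a mesenchymal phenotype that lacks the oestrogen receptor, was measured on 6 Affymetrix human genome arrays of the U133 series. On this array each transcript is read by 1 or more probe sets, groups of short oligonucleotides to which biotin-labelled RNA binds. Per the labels, cells received a siRNA against RhoGDIbeta or the control siRNA siLuc, were grown for 3 days and were lysed for total RNA, in 3 independent transfection experiments. Each experiment gave 1 siLuc and 1 siRhoGDIbeta array, so there were 3 arrays per group.

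The deposited series table holds 1 intensity per probe set and array on a linear scale, and the authors' algorithm and scaling target are not given in the sources used here. The mean of each array after trimming 2% at each end lay between 1500.4 and 1500.6, which is the form of a global scaling, and the values were therefore used as deposited. No array pair was identical. Per the file headers of the 6 scanner information files, all arrays were hybridised on the same day, scanned on the same day with the same scanner and came from the same chip lot. The arrays of experiments 1 and 2 were washed on fluidics station 1, and both arrays of experiment 3 on station 2 with another version of the washing protocol. Each station thus held both groups. The planned scan batch could not be used as a block because there was only 1 scan day.

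Of 22283 probe sets, 68 array controls were left out. In the platform annotation, 19065 of the remaining 22215 had 1 gene symbol, 1043 had several and 2107 had none. Gene IDs matched the RefSeq gene table (GRCh38.p14) for 19053, and 0 symbols needed updating. Probe sets with no or several symbols were tested but not named. No coordinates are given, since the files name no genome build. Values were taken as log2(intensity + 1), so fold changes are on that scale. The 1st percentile of intensity was 13.3 to 48.8 over the arrays, so the added 1 changes dim genes little. Differences of dim genes are therefore not conservative, and they have larger standard errors. Probe sets with a mean log2 value over the 6 arrays below the median of all were removed, which left 11108 probe sets of 6835 named genes. Detection calls were not used here.

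Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend on mean level, moderated two-sided test, Benjamini-Hochberg adjustment over all probe sets tested, threshold 0.05). Single values also had a two-sided exact permutation test of the group labels, which cannot go below p = 0.1 with 3 arrays against 3. Gene lists were tested with camera (preset correlation 0.01, 1 probe set per gene by the highest mean, at least 5 members above the filter), with camera using an estimated correlation and with fry beside it. Figures were drawn with matplotlib 3.10.9. Array numbers limit the precision of every value.

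The comparisons, the 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Named were ARHGDIB, the gene of RhoGDIbeta, and the 12 genes with the largest rise and the 12 with the largest fall past the threshold and the same way in the 3 experiments. Where fewer passed, the places went to genes with the smallest unadjusted p that differed the same way in the 3 experiments by at least 1.5-fold, given as values only. Further named were up to 4 members of each list with the smallest unadjusted p. Members above the filter of the list of prostaglandin synthesis and signalling were named in full. Of the 25 lists, 4 count towards the totals and the adjustment but are not described here. Of the list members so chosen, the text gives all 4 for the 3 lists with an unadjusted camera p under 0.05, and for the other lists those with an unadjusted p under 0.05 and the first of each, a shortening made after the values were seen. For a gene with several probe sets the one with the highest mean was used. Of the 513 list symbols, 471 had a named probe set.

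The experiment number pairs the arrays, since the labels say that it marks the shared transfection experiment. The deviations of same-numbered arrays from their group means correlated at 0.049, 0.027 and 0.010 across probe sets in experiments 1, 2 and 3, and an array correlated best with its own number only in experiment 1. The fit without the experiment as a block was set as the main one, and the block was an alternative. Other alternatives were median centring, quantile and cyclic loess normalization, pseudocounts of 16 and 64, no filter and a stricter filter, no variance trend, array weights, no _x_at probe sets, the mean of a gene's probe sets, an estimated correlation, and each array and each experiment left out in turn. The fluidics station as a block, and an estimated correlation under each setting in which a list passed, were added after seeing the data.

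The procedure was tested on simulated data with known changes in 50 probe sets per size. The noise was the residual SD of each probe set, divided by the square root of each array's weight (0.27 for siRhoGDIbeta 3). That SD already holds the spread of this array, so its noise was counted in both. For this comparison of 3 against 3 arrays, the procedure recovered 14% of changes of 1 on the log2 scale and 52% of changes of 2. It recovered 82% of changes of 4 and 90% of changes of 5 among 11108 probe sets, with 2 false calls. Noise was drawn independently across probe sets, so these rates are only a guide.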

Results

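Transcript levels were measured in MDA-MB-231 breast cancer cells 3 days after transfection with a siRNA against RhoGDIbeta or with the control siRNA siLuc. RhoGDIbeta, encoded by ARHGDIB, is a cytosolic GDP dissociation inhibitor. The data comprised 6 arrays, with 3 siLuc and 3 siRhoGDIbeta arrays from 3 independent transfection experiments. The question, as the title of the series puts it, was which genes respond to RhoGDIbeta in these cells.

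The arrays had been scaled to a common trimmed mean, but their distributions differed. Median intensity was 538.7, 514.7 and 474.8 on siLuc arrays 1, 2 and 3, and 619.9, 475.2 and 773.7 on siRhoGDIbeta arrays 1, 2 and 3. Array siRhoGDIbeta 3 correlated with the others across probe sets at 0.803 to 0.816, whereas the other 5 arrays correlated with each other at 0.904 to 0.951. Its 10th percentile was 112.4, against 41.2 to 66.4 on the others. The poly-A spike-in controls, added to RNA before labelling, had a mean log2 intensity of 12.52 ± 0.10 (SD, n = 3) on the siLuc arrays and 12.23 ± 0.13 (SD, n = 3) on the siRhoGDIbeta arrays (exact permutation p = 0.1, the smallest possible).

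**Figure D1:**
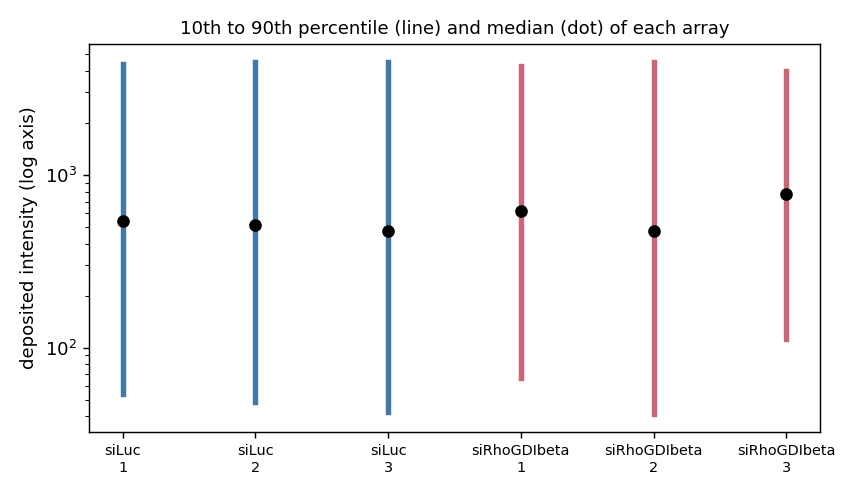
Deposited intensity (log axis) of all probe sets other than controls on each of the 6 arrays, as the 10th to 90th percentile (lines; blue, siLuc; red, siRhoGDIbeta) and the median (dots). On siRhoGDIbeta 3 the 10th percentile of 112.4 and the median of 773.7 lie above those of the other arrays.

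ARHGDIB, the targeted gene, was read by a single probe set. Its intensity was 6143, 5205 and 5732 in the siLuc cells and 39.3, 351.4 and 557.3 in the siRhoGDIbeta cells of experiments 1, 2 and 3. The mean log2 value was 12.47 ± 0.12 (SD, n = 3) with siLuc and 7.64 ± 2.02 (SD, n = 3) with siRhoGDIbeta, a 28.5-fold lower level (log2 difference -4.83, SE 0.78). The reading of 39.3 lay at percentile 3.18 of its array, near background, so this fold is not an exact size, and without that array the log2 difference was -3.68. It was lower in each of the 3 experiments, by -7.25 (the value that rests on the background reading), -3.88 and -3.36 on the log2 scale, and the arrays of the groups did not overlap (exact permutation p = 0.1, the smallest possible). In the limma fit across all probe sets it did not pass the threshold (adjusted p = 0.444). Without the filter on dim probe sets, the adjusted p was 0.045. Without siRhoGDIbeta replicate 1, the array with the lowest ARHGDIB value, it was 0.0031, and without siRhoGDIbeta replicate 3 it was 0.017. The mean difference was -5.57 within fluidics station 1 and -3.36 within station 2, with an adjusted p of 0.111 when station was a block.

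Across all genes, none passed the threshold. In limma, 0 of 11108 probe sets had an adjusted p below 0.05, and the smallest was 0.0875. At an unadjusted p under 0.05 there were 555 probe sets in this fit without a block, 269 higher and 286 lower with siRhoGDIbeta, and chance alone gives 555. Under the other settings, blocks included, there were 401 to 1224, the highest without the filter, where chance gives 1111. The count of 555 depended on single arrays, at 1404 without siRhoGDIbeta replicate 2 and 284 without siLuc replicate 2. Counted as genes, 349 of 6835 had an unadjusted p under 0.05, 149 higher and 200 lower, against 342 by chance. After median centring, which moves the median log2 difference of the tested probe sets from -0.04 to -0.30, 52 probe sets were higher and 349 lower. With the experiment as a block, 1 probe set passed. Without siLuc replicate 1, 11 probe sets passed, all higher with siRhoGDIbeta.

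The smallest p belonged to OLA1, which encodes Obg-like ATPase 1, a cytosolic ATP hydrolase. Its only probe set read 10955, 10189 and 11872 with siLuc and 2536, 1862 and 3908 with siRhoGDIbeta. This was 4.16-fold lower (log2 difference -2.05, SE 0.25, adjusted p = 0.0875 in limma), with differences of -2.11, -2.45 and -1.60 in the 3 experiments. With the experiment as a block the adjusted p was 0.019. With fluidics station as a block it was 0.0071, and the mean difference was -2.28 on station 1 and -1.60 on station 2. Without siRhoGDIbeta replicate 3 the adjusted p was 0.00104. It was not below the threshold throughout, and reached 0.706 under other settings and 0.793 with arrays left out.

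The fixed rule chose genes that differed the same way in all 3 experiments, so that agreement is no evidence for any of them. Of 6835 genes, 331 were higher and 297 lower in all 3 experiments by at least 1.5-fold. By chance 25% of genes agree in sign alone. The share expected when the 1.5-fold bound is added was not computed, so these counts cannot be set against it. The other genes named by the fixed rule did not pass, with adjusted p of about 0.81 in limma, and are given as values. Among those with a lower value in all 3 experiments, GLTP, a glycolipid transfer protein, was at 0.25 times its siLuc level (log2 difference -2.03, SE 0.45), MAN2A1, Golgi alpha-mannosidase II, at 0.56 times (-0.83, SE 0.17), ATP1B3, a beta subunit of the sodium-potassium pump, at 0.58 times (-0.80, SE 0.19), and ATP6AP2, an accessory protein of the vacuolar proton pump, at 0.56 times (-0.83, SE 0.22). LRP6, a Wnt co-receptor, was at 0.38 times (-1.41, SE 0.40). The mitochondrial genes NDUFB7, of respiratory complex I, and CYCS, cytochrome c, were at 0.41 (-1.28, SE 0.31) and 0.60 times (-0.73, SE 0.20). The remaining ones were ZNF146 (-0.71, SE 0.17), the metallothionein gene MT1H (-0.60, SE 0.16), whose probe set can also bind related transcripts, and NOTCH2NLA (-0.87, SE 0.21), which is nearly identical to part of NOTCH2, so its signal is uncertain.

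Among genes with a higher value in all 3 experiments, LIPE, hormone-sensitive lipase, was 6.64-fold higher (log2 difference 2.73, SE 0.59) and FUT7, a fucosyltransferase, 6.07-fold higher (2.60, SE 0.69), both from low siLuc intensities between 98.4 and 487.1. LIPE's other probe set, below the filter, went the opposite way (-0.68). CRYBG2 was 3.64-fold (1.86, SE 0.53), LBH 2.56-fold (1.35, SE 0.36), MID2, a ubiquitin ligase, 2.22-fold (1.15, SE 0.31) and PRX, periaxin, 2.20-fold higher (1.14, SE 0.33). CALU, the calcium-binding protein calumenin, was 1.98-fold (0.98, SE 0.19) and LMAN2, a cargo lectin, 1.75-fold higher (0.81, SE 0.23). DNAJC15, a mitochondrial co-chaperone, was 2.13-fold higher (1.09, SE 0.25), KDM5C, a histone demethylase, 1.92-fold (0.94, SE 0.26) and KCNN4, a calcium-activated potassium channel, 1.64-fold (0.72, SE 0.20). COL4A1 was 1.60-fold higher (0.68, SE 0.20), and its second probe set went the opposite way (-0.49). These 24 genes, ARHGDIB and OLA1 included, had 6 further probe sets above the filter, of which 5 had the same sign, and 8 below it, of which 4 did. The 5 belonged to CALU (0.75, 0.48 and 0.21), MID2 (0.19) and ATP6AP2 (-0.51). Each differed by less than the named probe set of its gene, so the sizes were not reproduced. Those with the opposite sign below the filter belonged to LIPE, NDUFB7 (0.58), ATP6AP2 (0.58) and LRP6 (0.14).

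**Figure D2:**
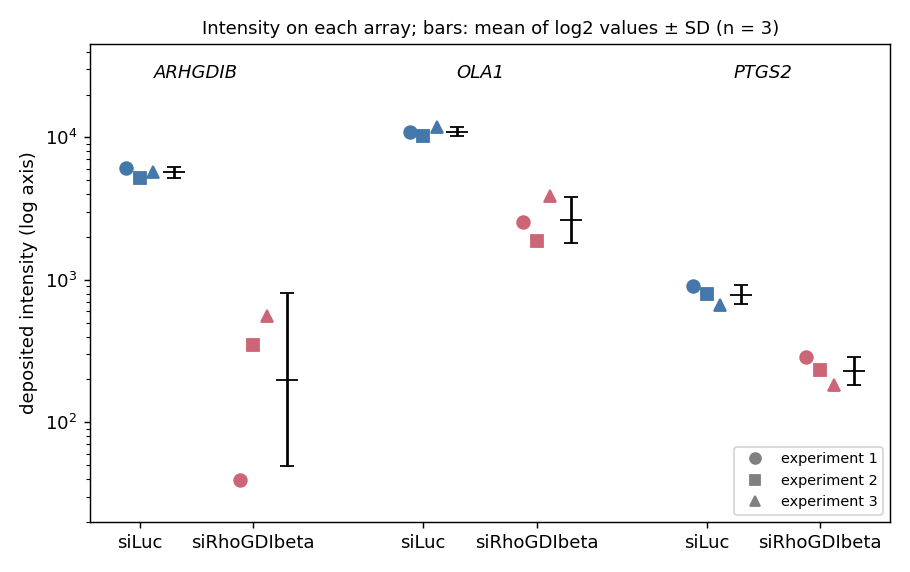
Deposited intensity (log axis) of ARHGDIB, OLA1 and PTGS2 on each array (blue, siLuc; red, siRhoGDIbeta; symbols, experiments), with the mean of the log2 values and its SD over 3 arrays in black. For each gene the 3 siRhoGDIbeta arrays lie below the 3 siLuc arrays.

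Genes of prostaglandin synthesis and signalling formed one of the lists. PTGS2, the inducible cyclooxygenase COX-2, had a mean log2 level of 8.73, just below the filter at 8.81, and is described outside the rule, chosen after its values were seen. Its intensity was 907.2, 796.1 and 667.0 with siLuc and 285.6, 231.8 and 182.2 with siRhoGDIbeta, a 3.41-fold lower level (log2 difference -1.77, SE 0.65). The difference was -1.66, -1.78 and -1.87 in the 3 experiments, -1.72 on station 1 and -1.87 on station 2 (exact permutation p = 0.1, the smallest possible; adjusted p = 0.835 in limma without the filter). Of the 6 list members above the filter, 0 passed, over all genes or adjusted over the list alone. PLA2G4A, the cytosolic phospholipase that releases arachidonic acid, was at 0.33 times its siLuc level (-1.58, SE 0.71, unadjusted p = 0.049), with -0.85 on station 1, -3.06 on station 2 and -0.81 without siRhoGDIbeta replicate 3. ABCC4, a transporter that exports prostaglandins, was at 0.55 times (-0.87, SE 0.49). PTGES3 (-0.24), PTGES2 (-0.30), PTGS1 (-0.05) and PTGES (0.21) differed by less than 1.5 times their standard errors. A second probe set of PTGES above the filter read 0.68. The list, tested on the 6 members above the filter and thus without PTGS2, lay -0.45 below other genes in log2 difference. It did not pass (camera adjusted p = 0.486, or 0.938 with an estimated correlation). The shift ranged from -0.74 (without siRhoGDIbeta replicate 2) to -0.30 (without both arrays of experiment 1). Its shift was -0.38 on station 1 and -0.58 on station 2, with a camera adjusted p of 0.548 with station as a block.

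Of the 22 lists with at least 5 members above the filter, 0 passed by camera, with the preset or an estimated correlation, and 3 had an unadjusted camera p under 0.05, all with an adjusted p of 0.169. Some of the lists counted are not described here. Extracellular proteolysis genes were 0.22 higher than other genes (p = 0.0105; estimated-correlation p = 0.076), with 13 of 18 members positive and 0 past the threshold or adjusted over the list alone. Its members at an unadjusted p under 0.05 were PLAT, tissue plasminogen activator (1.67-fold, log2 difference 0.74, SE 0.24), CTSD, cathepsin D (2.38-fold, 1.25, SE 0.45), and the matrix metalloproteinase genes MMP11 (1.63-fold, 0.70, SE 0.27) and MMP14 (1.57-fold, 0.65, SE 0.26), whose other probe sets above the filter read 0.39, -0.27 and 1.03. Mesenchymal and matrix genes were 0.15 higher than other genes (p = 0.023; estimated-correlation p = 0.133), with 10 of 15 positive and 0 past the threshold or adjusted over the list alone. Here the basement membrane collagen gene COL4A1 (second probe set -0.49) and the fibrillar collagen gene COL5A1 (1.53-fold, 0.61, SE 0.21, other probe sets 0.40 and -0.20) were higher. LOX, lysyl oxidase, was at 1.35-fold (0.44, SE 0.20, unadjusted p = 0.055 in limma, other probe sets 0.39 and 1.55). COL4A2 was at 0.70 times (-0.52, SE 0.21, other probe set -0.83). This list was the only one to pass fry's test for change in either direction (adjusted p = 0.0023; one-way test 0.376), which does not compare it with other genes.

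NF-kappaB and inflammatory genes lay -0.27 below other genes (p = 0.022; estimated-correlation p = 0.073), with 8 of 13 members negative and 0 past the threshold or adjusted over the list alone. IL1B, interleukin-1 beta, was at 0.66 times (-0.61, SE 0.21), PTX3, pentraxin 3, at 0.65 times (-0.62, SE 0.28), NFKB1 at 0.70 times (-0.51, SE 0.25, unadjusted p = 0.063). NFKBIE (-1.08, SE 0.60, unadjusted p = 0.102) rested on experiment 3, with -0.50, 0.13 and -2.86 in the 3 experiments. NFKBIE was at -0.27 and NFKB1 at -0.29 without siRhoGDIbeta replicate 3. PTX3 ranged from -0.82 to -0.35 with arrays left out. By fluidics station 1 and 2, the shift was 0.26 and 0.15 for proteolysis genes, 0.21 and 0.01 for matrix genes and -0.17 and -0.48 for inflammatory genes, and the camera adjusted p with station as a block was 0.131, 0.269 and 0.228. Without siRhoGDIbeta replicate 3, the array that stood apart, the proteolysis list passed (adjusted p = 0.0073), and without both arrays of experiment 3 the proteolysis (0.0097) and matrix (0.021) lists did. Other omissions made the matrix shift smaller, to 0.08 without siRhoGDIbeta replicate 2 (adjusted p = 0.662) and 0.05 without both arrays of experiment 2 (0.647). With an estimated correlation the lists that passed had adjusted p of 0.488, 0.777 and 0.777.

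**Figure D3:**
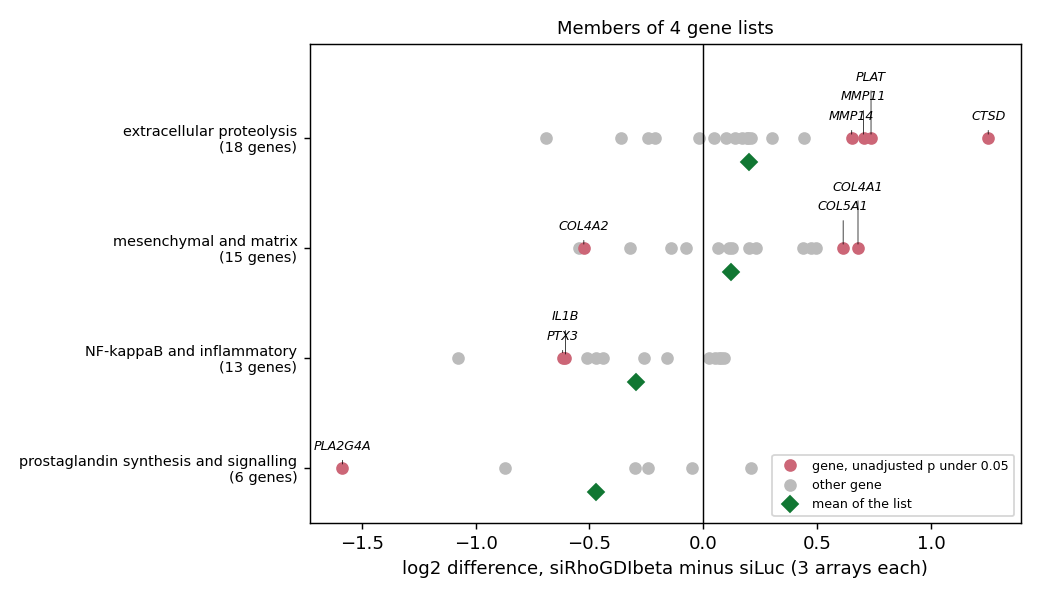
Log2 difference (siRhoGDIbeta minus siLuc, 3 arrays each) of the members above the filter of 4 gene lists, with genes at an unadjusted p under 0.05 named and in red, other genes in grey and the mean of each list as a green diamond. PLAT, CTSD, MMP11 and MMP14 lie to the right of 0, and IL1B, PTX3 and PLA2G4A to the left.

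The SRF and YAP targets (adjusted p = 0.955) had a mean log2 difference below 0 (-0.07), while camera pointed upwards. In this list CCN2, a secreted matrix-associated growth factor (-0.76, SE 0.30), also the first of the breast cancer metastasis genes (adjusted p = 0.813), and CCN1 (-0.43, SE 0.18) had an unadjusted p under 0.05. CCN2 was at -0.38 without siRhoGDIbeta replicate 3, the array that stood apart.

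Proliferation and stress lists did not pass either. The camera adjusted p was 0.715 for mitosis, 0.699 for DNA replication, 0.973 for CDK inhibitors and p53 targets, 0.948 for the unfolded protein and integrated stress response, 0.955 for hypoxia and glycolysis, 0.354 for cholesterol synthesis and 0.699 for the type I interferon response. Their members at an unadjusted p under 0.05 were TPX2, a spindle factor (0.58, SE 0.23), the replicative helicase gene MCM4 (-1.17, SE 0.41; its 3 other probe sets were positive), GADD45A (-0.62, SE 0.27), PMAIP1 (-0.70, SE 0.30), HSP90B1 (-0.78, SE 0.30; other probe set 0.13), ALDOA (-0.42, SE 0.15), MVK (0.58, SE 0.26; other probe sets -0.36 and 0.40) and OAS3 (1.47, SE 0.57). Without siLuc replicate 3, the DNA replication list passed with the preset correlation (adjusted p = 0.00021) but not with an estimated one (0.702). The immediate early genes (0.864), the ETS factors and PTHrP (0.955) and the growth factors and receptors (0.818) held SPRY2 (0.70, SE 0.26), EGR1 (-0.95, SE 0.39), DUSP5 (0.51, SE 0.21), ELF3 (1.38, SE 0.62; other probe set, below the filter, -1.08), FGFR1 (0.67, SE 0.25; other probe sets above the filter -0.36 and -0.21) and PDGFC (-0.38, SE 0.16) at an unadjusted p under 0.05. PMAIP1 was at -0.32 and HSP90B1 at -0.47 without siRhoGDIbeta replicate 3. In these lists 0 members passed over all genes tested or adjusted over the list alone.

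The remaining lists concerned cell identity and the siRNA machinery. The camera adjusted p was 0.772 for epithelial junction and keratin genes, first among them CLDN7 (-0.36, SE 0.27), 0.553 for luminal breast cell markers, first GATA3 (0.82, SE 0.43), and 0.772 for the RNA interference machinery, first DICER1 (-0.38, SE 0.26; -0.24 without siRhoGDIbeta replicate 3). Without the filter, 11 of 20 epithelial genes were higher and 9 lower. The dim EPCAM (3.24, unadjusted p = 0.012 in limma) and CDH1 (2.99, unadjusted p = 0.017) are given outside the rule, chosen after their values were seen. Both were higher in all 3 experiments but not past the threshold (adjusted p = 0.835 for each). Their siLuc readings went down to 16.8 and 13.0, near background, so these sizes are not exact. The dim blood cell markers LYZ (2.96, unadjusted p = 0.017) and PTPRC (2.51, unadjusted p = 0.045) were likewise higher in all 3 experiments. Blood cell and fibroblast markers had 2 members each above the filter and were not tested, with CD53 at 0.27 (SE 0.51) and THY1 at 1.23 (SE 0.72). Without the filter, 10 of 12 blood cell markers (median log2 difference 0.74) and 10 of 11 fibroblast markers (1.08) were higher, most of them dim. Random lists matched on level also lay higher, with medians of 0.315 and 0.268, and the markers were at percentiles 91.4 and 99.1 of them. Without siRhoGDIbeta replicate 3, the array with the raised low end, 7 of 12 blood cell (0.33) and 6 of 11 fibroblast markers (0.17) were higher, at percentiles 79.8 and 62.5. In these lists too, 0 members passed over all genes or adjusted over the list alone.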

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

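Of the alternatives, the fluidics station block and the estimated correlation under other settings were chosen after seeing the data. The count of 0 probe sets became 1 with the replicate block (OLA1) and 1 with the station block (OLA1), and 2 each with a pseudocount of 64, without the filter and with array weights (ARHGDIB and OLA1 in each case). It ranged from 0 to 11 with arrays or experiments left out, with 11 without siLuc replicate 1, 2 without siRhoGDIbeta replicate 3, 2 without replicate 1, and 1 each without siRhoGDIbeta replicate 1 and without replicate 3. At an unadjusted p under 0.05, 555 probe sets became 1224 without the filter (776 higher, 448 lower, where chance gives 1111), and between 263 and 1404 with arrays left out, 263 without replicate 1 and 1404 without siRhoGDIbeta replicate 2. ARHGDIB kept its direction under every setting (-5.63 to -4.26, and -5.57 to -3.62 with arrays left out). It passed with a pseudocount of 64 (-4.26, adjusted p = 0.044), without the filter (-4.83, 0.045), with array weights (-5.63, 0.0037), and without siRhoGDIbeta replicate 1, siRhoGDIbeta replicate 3 or replicate 1. Its adjusted p ranged from 0.0031 to 0.976. OLA1 ranged from -2.34 to -1.80, with an adjusted p of 0.00059 to 0.793. The count of 0 lists became 2 with quantile normalization and 2 with cyclic loess (proteolysis and matrix) and 1 with array weights (proteolysis), and ranged from 0 to 2 with arrays left out. With an estimated correlation none of these lists passed (smallest adjusted p 0.314). The cause was not tested. The replicate block changed no other call. PTGES reversed after median centring (-0.052), small against its error, and this scaling lowers all differences. With arrays left out, PTGES ranged from -0.071 (without replicate 1) to 0.37, PTGES2 from -0.52 to 0.027, PTGS1 from -0.38 to 0.43 and CD53 from -0.15 to 0.90. The other named genes, and the 4 lists given with a direction, kept it under every setting in which they had a value. Single genes had no value under the mean of a gene's probe sets, where only lists were followed. Genes whose probe sets disagree were thus not tested in this way, such as MCM4 (other probe sets 0.66, 0.52 and 1.14), COL4A1 (-0.49) and FGFR1 (above the filter -0.36 and -0.21). No gene but ARHGDIB and OLA1 among them passed under any. Of 60 genes followed without siRhoGDIbeta replicate 3, 7 kept their sign but differed by over 1.5 times less. LIPE and THY1 had no value there. With arrays left out, sizes of other genes fell as well, to -0.20 for CLDN7, -0.40 for GADD45A and 0.85 for ELF3 at the smallest. For the other lists described only the adjusted p was followed, and DNA replication alone crossed the threshold, without siLuc replicate 3.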

Other observations

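All tests in this part were chosen after the results were seen, except the tests of noise and transcript levels on siRhoGDIbeta 3 and of the agreement between probe sets. Gene families, picked because CYCS, NDUFB7, ATP6AP2 and MT1H were among the named genes, showed small differences in 1 direction. Of 45 genes of respiratory chain complexes I, III and IV and cytochrome c above the filter, 40 had a lower value with siRhoGDIbeta, by -0.24 on average, with 8 at an unadjusted p under 0.05, all lower. The mean was -0.20, -0.08 and -0.45 in experiments 1, 2 and 3, where experiment 3 was washed on its own fluidics station. Genes of the vacuolar ATPase, the proton pump of lysosomes, were lower in 15 of 16 cases (-0.24), and metallothionein genes, whose probe sets can bind each other's transcripts, in 6 of 6 (-0.36). The camera adjusted p over these families was 9.9e-06, 0.0088 and 0.00055, but with an estimated correlation the unadjusted p was 0.12, 0.10 and 0.15. Bright genes as a whole were lower: random lists matched on level had a median of -0.09, -0.07 and -0.11, and the families lay at percentiles 0.01, 2.5 and 0.12 of 10000 such lists. Under median centring, quantile and cyclic loess scaling the respiratory chain mean was -0.51, -0.18 and -0.16, with 44, 33 and 31 of 45 lower and an estimated-correlation p of 0.41, 0.075 and 0.016. Without siRhoGDIbeta replicate 3 it was -0.16, with 32 of 45 lower, and the means of the vacuolar ATPase and metallothionein genes were -0.16 (13 of 16) and -0.19 (5 of 6). Of the 10 splits of the arrays, the real one gave the largest mean for each of the 3 families (0.24, 0.24 and 0.36 in size, the next 0.19, 0.20 and 0.34), and 10 splits are too few to exclude chance. The genes that led to the choice of these 3 families stayed in them. Their split ranks, percentiles and camera p thus partly restate that choice, and random lists do not carry the correlation among family members. The 52 ribosomal protein genes averaged -0.01, with 31 lower, at percentile 100 of matched lists with a median of -0.12, but camera gave p = 0.366 (0.781 with an estimated correlation) and all 10 splits a mean at least as large in size. Their direction turned with the scaling, at -0.27 (49 lower), 0.03 (25) and 0.10 (20) under median centring, quantile and cyclic loess.

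The 11 probe sets that passed without siLuc replicate 1 included 8 named ones, 5 of ribosomal protein genes (RPLP2, RPL27A, RPS10, RPL14 and RPL38), and were chosen here after their values were seen. Their mean log2 level was 13.91, 10.79 and 11.46 on siLuc arrays 1, 2 and 3 and 13.78, 13.48 and 13.61 on the siRhoGDIbeta arrays. The array's probe sets for 18S and 28S ribosomal RNA read 12.93, 10.14 and 11.18 on the siLuc arrays and 12.84, 12.05 and 12.81 on the siRhoGDIbeta arrays. Another probe set of RPL14 did not follow them, at 14.89, 15.03 and 15.11 against 14.86, 15.07 and 14.33.

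Array siRhoGDIbeta 3 stood apart from the other 5. If its RNA truly differed, 2 probe sets of 1 gene would deviate together. Over 2124 genes these deviations correlated at 0.139, below the bound of 0.3 set in advance. The prediction for measurement noise was thus met, and that for different transcript levels was not. The correlation was 0.074 to 0.202 on the other arrays, so every array lay below that bound. No array with known transcript differences showed what correlation these give, so the test cannot tell noise from different transcript levels. The covariance was higher on this array (0.098 against 0.021 to 0.039), so a part that the probe sets share stays open. An exchange with a siLuc sample is argued against by ARHGDIB, which lay 3.22 log2 units below the lowest siLuc array.

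The lower OLA1 signal may be an effect of RhoGDIbeta loss or of the siRNA itself. Chance stays open too, since OLA1 did not pass in the planned fit (adjusted p = 0.0875 in limma). Scaling is argued against, since the highest value over 3 other scalings was -1.95. The smallest of the 3 differences between paired arrays was -1.60. OLA1 was picked for its small p and the same direction in all 3 experiments, which favours such agreement, so this decides little about a single deviating array. Binding of the siRNA to the OLA1 transcript stays open, because the siRNA sequence was not used here and only 1 probe set read the gene. A second siRNA would be needed to tell an effect of RhoGDIbeta loss from one of the siRNA itself.

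The proteolysis and matrix lists, joined after their shifts were seen, held 33 genes with a mean log2 difference of 0.16, and of 0.22 without siRhoGDIbeta 3, which argues against that array as the source. The camera p was 0.0013 with all arrays and 4.4e-05 without that array (0.057 and 0.018 with an estimated correlation), but these p partly restate the choice of the lists, which were joined because both lay higher. Brightness is argued against too, because random lists matched on level had a median of -0.07, of the opposite sign, and the joined lists lay at percentile 100 of them, a rank that their choice also raises. A response of matrix-remodelling genes is a hypothesis that these data do not settle, since neither list passed in the planned fit, and those that passed under other settings did not pass there with an estimated correlation, and RNA of other cells was not tested as a source. Fibroblast markers, mostly dim, had a median of 1.08 with all arrays (percentile 99.1 of lists matched on level) and 0.17 without siRhoGDIbeta 3 (62.5).

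Other splits of the 6 arrays into 3 and 3 cannot exclude chance, since there are only 10. The real split gave 0 probe sets and 0 lists past the threshold. That 10 of 10 splits gave as many probe sets and 10 of 10 as many lists follows from these counts of 0 and decides nothing. The highest other split gave 0 and 3. The 3 others that part all 3 pairs gave 0 lists and 194 to 509 probe sets at an unadjusted p under 0.05, against 555, and the 6 that part 1 pair gave 0 to 3 lists and 174 to 862 probe sets. The log2 difference between groups correlated between 2 probe sets of a gene at 0.142 in the real split, against 0.103 at most in the others that part all pairs. The correlation was higher in 2 other splits, at 0.189 and 0.177, each of which keeps 2 pairs together. The prediction set in advance for real differences between the arms, that no other split be as high, was therefore not met. Whether such splits carry differences between experiments was not tested. Deviations of same-numbered arrays from their group means correlated at only 0.049, 0.027 and 0.010. Whether the arms differ in many genes by small amounts stays open.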
